A study of Mus musculus with 6 samples.

How the data were processed

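Total RNA from liver of 24-month-old C57BL/6 mice with a hepatocyte-specific deletion of Srsf3 was labelled with biotin and hybridised to Affymetrix arrays, 1 array per sample. The labels placed 3 arrays with non-tumorous liver (numbers 405, 483 and 623) and 3 with hepatocellular carcinoma (numbers 405, 483 and 616), and each sample is named here by its group and number. The deposited values were intensities on a linear scale, summarised and normalized by the authors with PLIER, per the labels, on the mm9 genome, per the submitters' processing notes. The version of PLIER was not given in the sources used here. The labels call the values full exons, but the feature numbers were those of the gene-level design of the array, so no test of exon use within a gene was made. The planned exon list and the exon-use results were therefore not analysed here.

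The table held 238609 features, of which the platform annotation gave 24343 exactly 1 gene symbol, 1797 several and 212469 none. Of those with 1 symbol, 23782 were matched by Entrez number to the mouse gene table used here. The other 561 kept the annotation's symbol, and 0 symbols differed between both sources. Features with several symbols named no gene. Values were taken as log2(intensity + 16), so differences of dim genes are understated. A feature was kept if its mean over all 6 arrays was at or above the 25th percentile of features with a gene, an intensity of 55.5. The median over the kept features of a symbol gave the gene value, for 17024 genes from 18534 features. In 1197 genes over 1 feature was kept, and in 38 of these the features differed by more than 1 log2 unit in the group difference.

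The design had assumed arrays brought to one distribution, but the array medians of the gene values spanned 1.20 log2 units. The test planned before the data were examined was kept as written, on the values as deposited. The planned quantile normalization (17020 genes) is given beside it throughout, since every single-gene call depended on this choice. Tumour was compared with non-tumour by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) over all 6 arrays without covariates, with Benjamini-Hochberg adjusted p under 0.05. Differences are tumour minus non-tumour and, on the deposited scale, are given relative to the median gene, while the planned test is of the difference itself. A test of the relative difference with the same SE was added. The prior degrees of freedom came out infinite as deposited, so that every gene was given the variance of the trend, and 3.62 after quantile normalization.

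The same steps were tested on simulated data with the real genes' means, 17014 genes in 5 draws, with 100 genes changed 2-fold and 100 changed 4-fold in each. On the deposited scale 24.6% of the 2-fold and 66.8% of the 4-fold changes were found, and between 132 and 163 unchanged genes per draw were called in error. After quantile normalization 16.4% and 69.0% were found, with 1 to 8 unchanged genes called in error. A shifted list of genes was recovered in 5 of 5 draws and an unshifted one was called in 0 of 5 on either scale. The simulated genes were drawn independently of each other, so these draws do not test the list calls where genes are correlated. The excess of wrong calls on the deposited scale was not removed, because the main test had been fixed.

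Lists of genes were written down in advance for the tissue: oncofetal and HCC-associated genes, hepatocyte identity, urea cycle and amino acid breakdown, cytochrome P450 and xenobiotic metabolism, bile acid synthesis and transport, cholesterol synthesis, fatty acid and triglyceride synthesis, fatty acid oxidation and ketogenesis, cell cycle, mesenchymal transition, beta-catenin targets and pericentral genes, periportal genes, acute phase, interferon response, unfolded protein and integrated stress response, p53 and DNA damage response, SR proteins and splicing regulators, insulin and IGF axis, imprinted genes, oxidative stress and NRF2 targets, glycolysis and hypoxia, male-biased and female-biased liver genes, mitochondrial respiratory chain, ribosomal proteins, and growth signalling and oncogenes. Markers of other cell types covered extracellular matrix and stellate cells, cholangiocytes and progenitors, Kupffer cells and macrophages, lymphocytes, neutrophils, endothelial cells, erythroid cells, and adipocytes and muscle. The 34 lists with at least 5 measured genes were tested with camera (limma, preset inter-gene correlation 0.01), adjusted over the lists. Camera with an estimated correlation and fry were the alternatives. In the sex chromosome list only Xist passed the filter on dim features, and it was not tested as a list.

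The genes named were set by rule. They were Srsf3, the 10 genes with the largest difference in each direction among those that passed the test without overlap between the groups, a fixed set of liver and tumour genes, and from each list up to 4 members with the smallest p together with any member that passed. Where fewer than 10 passed, genes without overlap and with the smallest unadjusted p filled the set and are said not to pass. Predicted genes and clones were counted but not named. Spp1, in the fixed set, was too dim to be tested. Members named for other reasons are said to have been chosen after their values were seen.

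The alternatives were median centring of each array, the mean or the brightest feature of a gene, other filters on dim features, pseudocounts of 1 and 64, eBayes without a trend or robust, array weights, the sample number as a replicate block, other thresholds, and each array left out in turn. The brightest feature, each gene's own variance, the test of the relative difference and the combinations of quantile normalization with another change were added after the data had been seen. The criteria of 2 tests of explanations were revised after a first version had been run and its values seen. The test of array scale first used quantile normalization alone, under which the scale would have been taken as the cause, and now needs median centring to agree. The test of male tumours first took 1 value per Y-linked gene, and now takes every feature above the dim threshold in non-tumour 623. Numbers 405 and 483 occurred in both groups, but the labels do not say what a number stands for, so the main test has no block. Figures were drawn with matplotlib 3.10.9.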

Results

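Gene expression was measured in liver of 24-month-old mice whose hepatocytes lacked Srsf3, the gene of a serine- and arginine-rich splicing factor. The samples were 3 pieces of non-tumorous liver (non-tumour 405, 483 and 623) and 3 hepatocellular carcinomas (tumour 405, 483 and 616), with 1 array each. All 6 came from knockout animals, and no array of liver with intact Srsf3 was analysed here. Apart from these numbers, the labels do not say whether the samples of a group came from separate animals. The p-values therefore cannot be read as the spread between animals. As deposited, limma gave every gene the variance of the intensity trend, so single-gene p-values and SE do not measure that gene's own spread between samples. In the 52 genes called below, the own SD was a median of 2.69 times the one used. The number of arrays limits the precision: an exact permutation test of 3 against 3 samples cannot go below p = 0.1.

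Srsf3 lay at 10.26, 10.19 and 10.20 log2 units in non-tumour 405, 483 and 623, and at 10.60, 10.69 and 9.85 in tumour 405, 483 and 616. The group means were 10.22 ± 0.04 and 10.38 ± 0.46 (SD, n = 3 each), and the difference did not pass the test (limma, adjusted p = 0.877). The place of this feature relative to the deleted exons was not given in the sources used here, so its level checks neither the deletion nor the labels. The difference was 0.29 ± 0.39 (SE) after quantile normalization, and -0.06 when non-tumour 623 was also left out. With the gene's dim features included it was -0.19 as deposited, where the median gene stood at -0.46.

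The arrays differed in their median intensity. Median intensities of features with 1 gene symbol were 183, 122 and 197 in non-tumour 405, 483 and 623, against 83.6, 151 and 98.6 in tumour 405, 483 and 616. The median gene stood at -0.48 log2 units in tumour relative to non-tumour on the deposited scale, against -0.03 after quantile normalization, and changes on the deposited scale are given relative to that median gene. The adjusted p on that scale tests the difference before the median gene's was taken off. The relative difference was also tested, with the same SE, and its adjusted p is called relative below. The groups did not differ alike at every intensity. The 25th percentiles were 85.1, 53.5 and 76.0 in non-tumour 405, 483 and 623, against 36.0, 62.4 and 40.0 in tumour 405, 483 and 616. The 99th percentiles were 2738, 2772 and 4624 against 2967, 3318 and 3489. The median gene's difference is therefore a poor reference for bright genes.

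**Figure D1:**
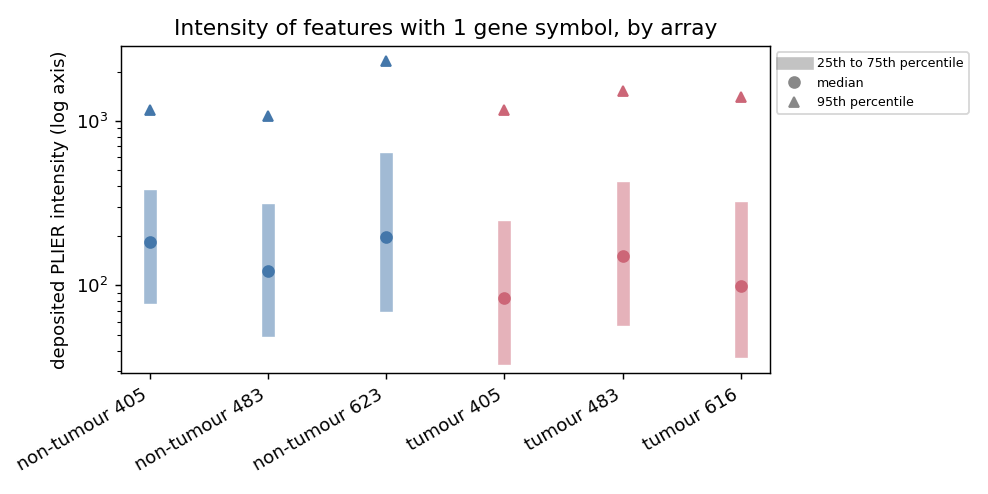
Deposited intensity (log axis) of features with 1 gene symbol on each of the 6 arrays, with the median as a circle, the 25th to 75th percentile as a bar and the 95th percentile as a triangle (non-tumour blue, tumour red). Medians ran from 83.6 in tumour 405 to 197 in non-tumour 623.

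The comparison of tumour with non-tumorous liver asked which genes differ in the carcinomas that arise in this model. Igf2bp3, an RNA-binding protein of fetal liver and of many carcinomas, rose by 2.85 ± 0.42 log2 units in tumour (SE, n = 3 each, limma adjusted p = 3.0e-05, relative 5.37e-08). Cib3, a calcium-binding protein of the CIB family, rose by 2.86 ± 0.49 (adjusted p = 0.00084, relative 6.42e-06). Every tumour array lay above every non-tumour array for both genes, but neither call outlasted the omission of every array: Igf2bp3 did not pass without non-tumour 483 (adjusted p = 0.189), nor Cib3 without non-tumour 405 (0.291) or tumour 616 (0.102). Before the median gene was taken off, Igf2bp3 then stood at 1.53 against 2.37 with all arrays, and Cib3 at 1.90 and 2.12 against 2.38. Ppargc1a, the coactivator of mitochondrial and gluconeogenic genes, fell by 2.74 ± 0.50 (adjusted p = 3.83e-07, relative 5.26e-05; 0.0811 without tumour 405), and Zfhx4, a zinc-finger homeobox transcription factor, fell by 2.05 ± 0.41 (adjusted p = 1.46e-06, relative 0.000445). Dmbt1, a secreted scavenger receptor of epithelia, fell by 3.34 ± 0.39 (adjusted p = 7.45e-19, relative 8.76e-14), although after quantile normalization non-tumour 405, at 5.36, lay just below tumour 483, at 5.38.

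The other genes in the set of 10 lower without overlap as deposited were Gldn (-2.56), which encodes the cell-adhesion protein gliomedin, Miox (-2.05), the myo-inositol oxygenase, Lepr (-1.68), the leptin receptor, Tox (-1.68), an HMG-box transcription factor, Gnat1 (-1.67), a transducin subunit, Bend7 (-1.62), a BEN-domain protein, and Slc43a1 (-1.55), a transporter of neutral amino acids. Their adjusted p-values ran from 2.72e-11 for Gldn to 0.033 for Tox. Relative to the median gene Lepr (relative adjusted p = 0.336), Tox (0.347), Slc43a1 (0.260) and Bend7 (0.0516) did not pass, and after quantile normalization the groups overlapped for Lepr and Tox. Among genes higher in tumour, the next 8 without overlap did not pass: Glod5 (1.74), a glyoxalase-domain protein, Smpdl3b (2.04), a lipid-modifying phosphodiesterase, Fabp4 (2.15), Uqcc2 (1.73), an assembly factor of complex III, Aspn (1.44), a matrix proteoglycan, Ghitm (1.84), an inner mitochondrial membrane protein, Rpp38 (1.54), a subunit of RNase P, and Zfas1 (1.60), a non-coding host of small nucleolar RNAs, with adjusted p from 0.152 for Glod5 to 0.457. Relative to the median gene Glod5 (relative adjusted p = 0.00300) and Smpdl3b (0.0321) passed, and after quantile normalization the groups overlapped for Ghitm. Fabp4, a fatty acid carrier of adipocytes and capillary endothelium, lay at 10.85 ± 0.22 in tumour against 9.18 ± 0.74 in non-tumour (SD, n = 3 each).

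In all, 14 genes were higher and 38 lower in tumour among 17024 tested as deposited (limma, adjusted p under 0.05), and 1 of these 52 was a clone with no gene name. Only 19 of the 52 had groups that did not overlap, 2 higher and 17 lower; over all genes 23 higher and 2017 lower did, 12.0% against 10% by chance. On the other scales fewer than chance gives did, 610 and 747 (7.97%) after quantile normalization and 211 and 1054 (7.43%) after median centring. Tested relative to the median gene, 33 genes were higher and 12 lower, among them 26 of the 52, the 14 higher and 12 of the lower. That test took the same constant off every gene and reused the pooled variance, so it is not an independent check of the calls. After quantile normalization limma called 0 genes higher and 0 lower (smallest adjusted p = 0.916), with 441 higher and 174 lower at an unadjusted p under 0.05, against 92 and 1429 as deposited. Median centring, which also takes off the middle of each array, gave 0 and 0, with 184 and 263 unadjusted. Its prior degrees of freedom were 4.02, not infinite. Chance alone would give 851 genes at an unadjusted p under 0.05. After quantile normalization and after median centring both directions together gave fewer. All 52 genes kept their direction after quantile normalization, with a median size of 1.87 log2 units against 2.09, but the median SE grew from 0.42 to 0.82. The 52 had been selected for large differences on these same arrays, so their kept direction gives no support to the calls. In simulated data of this design the test as deposited called at least 132 unchanged genes in error, more than the 52 found here.

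Single arrays moved these counts. The 14 and 38 became 9 and 37 without non-tumour 405, 7 and 99 without non-tumour 483, and 98 and 43 without non-tumour 623. They became 12 and 8 without tumour 405, 22 and 405 without tumour 483, and 6 and 20 without tumour 616. Of 15 genes called in the named set and the fixed set, 4 passed whichever array was left out: Dmbt1, Gldn, Zfhx4 and Gpc3. Each of these fits again gave every gene the variance of the trend, so passing does not show that the samples of a group agreed. Gpc3 passed although its groups overlapped, with non-tumour 483 at 6.67 and tumour 483 at 6.83 as deposited. The sizes of the 4 genes moved all the same. Before the median gene was taken off, as in the rest of this paragraph, Dmbt1 ran from -5.30 without non-tumour 405 to -2.32 without non-tumour 623 (-3.82 with all arrays), Gldn from -3.90 to -2.16 (-3.04), Zfhx4 from -2.85 to -2.17 (-2.53) and Gpc3 from -5.56 to -2.62 (-3.84). Dmbt1 lay at 5.79, 8.73 and 11.75 in non-tumour 405, 483 and 623. Without tumour 405 Gnat1 (-1.87 against -2.15, adjusted p = 0.0683), Bend7 (-1.50 against -2.10, 0.968) and Ppargc1a (-2.43 against -3.22) did not pass. Without non-tumour 405 Miox did not (0.572): it lay at 11.16 there, against 5.80 and 6.81 in non-tumour 483 and 623, and its difference went from -2.53 to -0.92. Slc43a1 did not pass without non-tumour 405, tumour 405 or tumour 616 (adjusted p from 0.259 to 0.968), and neither did Lepr (0.069 to 0.694) or Tox (0.152 to 0.968), which also failed without non-tumour 483 (0.206 and 0.0678). In some of these the size was kept and only the call was lost: Lepr stood at -2.41 without non-tumour 405 and -2.27 without tumour 616 (-2.17 with all arrays), Tox at -2.16 and -2.21 (-2.16), and Slc43a1 at -2.01 without tumour 616 (-2.03). The smallest sizes were -1.24 for Lepr without non-tumour 483, and -1.44 for Tox and -1.59 for Slc43a1 without tumour 405.

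**Figure D2:**
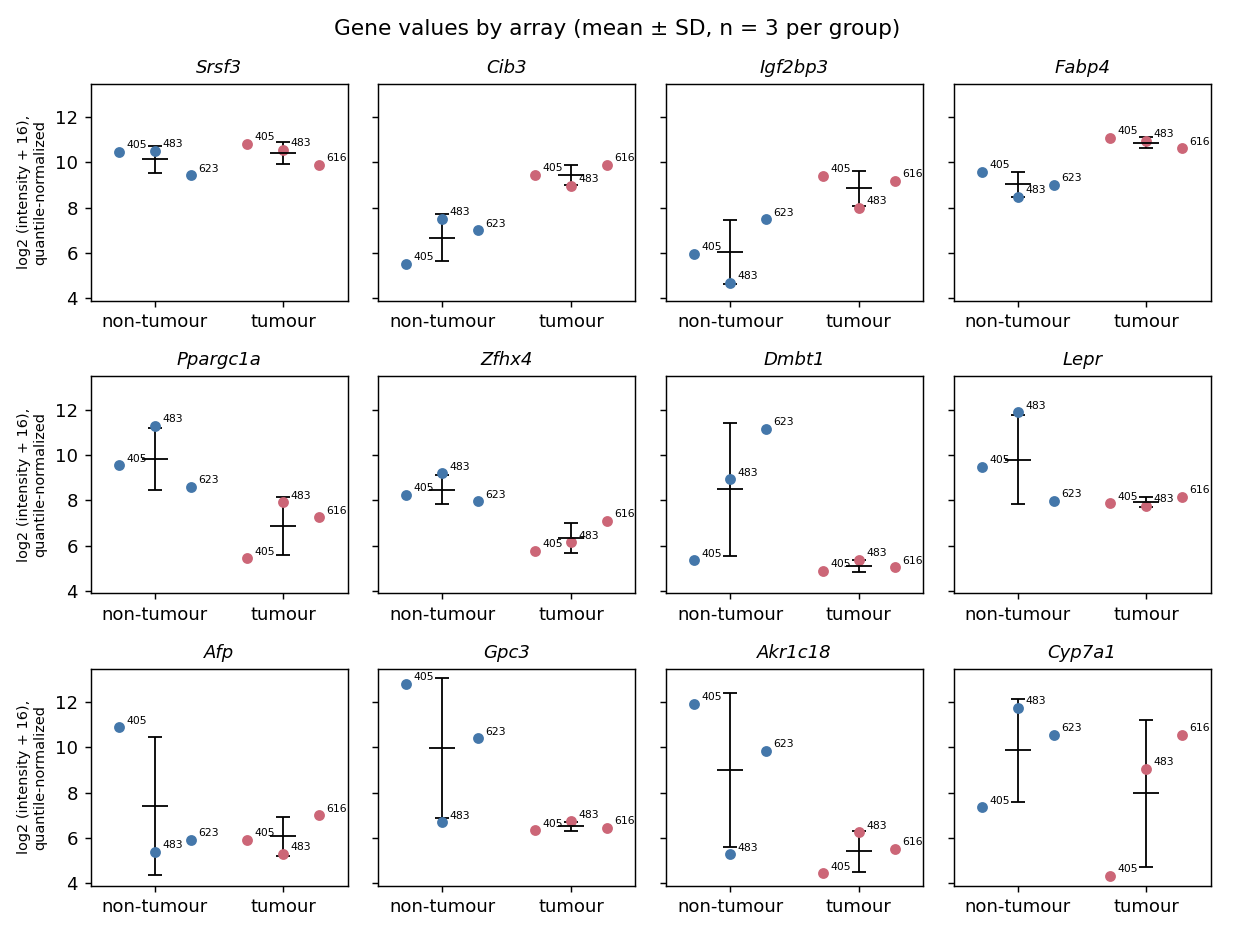
Quantile-normalized log2 (intensity + 16) of 12 genes on each array (non-tumour blue, tumour red, numbers beside the points), with the group mean and SD (n = 3). Cib3 lay between 5.52 and 7.52 in non-tumour and between 8.98 and 9.89 in tumour, whereas Gpc3 ranged from 6.70 to 12.80 within non-tumour.

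Oncofetal genes did not share one direction. Akr1c18, an aldo-keto reductase, fell by 3.42 ± 0.40 (SE, limma adjusted p = 2.0e-18, relative 1.28e-13), and Gpc3, the fetal proteoglycan glypican 3, fell by 3.36 ± 0.49 (adjusted p = 2.72e-11, relative 4.97e-08). Afp, alpha-fetoprotein, passed before the median gene was taken off (-1.56, adjusted p = 0.0203) but not relative to it (-1.08 ± 0.38, relative 0.544). All 3 were highest in non-tumour 405, where Afp stood at 10.90 after quantile normalization against 5.39 and 5.92 in non-tumour 483 and 623 and at most 7.01 in a tumour. Without non-tumour 405 the difference of Afp, before that of the median gene was taken off, was 0.07 (adjusted p = 0.927), and Afp did not pass without tumour 405 either (0.586). Gpc3 stood at 12.80 in non-tumour 405, 6.70 in non-tumour 483 and 10.40 in non-tumour 623, against 6.34 to 6.75 in the tumours, and Akr1c18 at 11.92, 5.29 and 9.86, against 4.45 to 6.26. Igf2, the fetal insulin-like growth factor, did not pass (relative difference 1.19, adjusted p = 0.457). It stood at 11.89 in tumour 483, 8.74 in tumour 616 and 4.63 in tumour 405. H19, the maternally expressed neighbour of Igf2, did not pass either (adjusted p = 0.180) except relative to the median gene (2.07, relative 0.0123), with non-tumour 483 at 7.28 and the other arrays between 11.13 and 12.75. Over the oncofetal list of 17 measured genes 1 was called higher and 3 lower over all genes, and 3 and 3 adjusted over the list alone, before the median gene was taken off. After quantile normalization limma called 0 of them, also over the list alone, with 1 higher and 2 lower unadjusted. The list as a whole did not pass (camera adjusted p = 0.158), and its median was -0.09 where its mean was 0.04 and its test pointed up.

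Of the other liver and tumour genes fixed in advance, 1 passed the test. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, passed before the median gene was taken off (-2.20, limma adjusted p = 0.0358) but not relative to it (-1.72 ± 0.57, SE, relative 0.364), with tumour 405 at 4.34 and tumour 616 at 10.55 after quantile normalization. It did not pass without non-tumour 483 (-1.52, adjusted p = 0.206), non-tumour 623 (-1.68, 0.0512) or tumour 405 (-0.31, 0.971). Alb (0.44, adjusted p = 0.947), the albumin gene, and Hnf4a (0.22, adjusted p = 0.716), a regulator of hepatocyte identity, did not pass. Nor did Insr (-0.49), the insulin receptor, Igf1r (0.80), the receptor of Igf1, Igf1 itself (0.04), a growth factor made by hepatocytes, Myc (0.57), a proto-oncogene, Ctnnb1 (0.12), the beta-catenin gene, Glul (-0.16), the glutamine synthetase of pericentral hepatocytes, or Mki67 (-0.06), a marker of cycling cells. The matrix genes Col1a1 (0.37) and Fn1 (-0.22), the cholangiocyte keratin Krt19 (0.08), the macrophage marker Adgre1 (-0.91), the endothelial marker Pecam1 (0.91) and the T-cell gene Cd3e (-0.42) did not pass, with adjusted p between 0.457 and 0.936 over these 13 genes. Before the median gene was taken off, Ctnnb1 (-0.36), Igf1 (-0.44) and Hnf4a (-0.26) were negative, as after quantile normalization (-0.28, -0.36 and -0.21). Glul was the median of 2 features that differed. As deposited the brighter lay at 8.30, 10.44 and 10.65 in non-tumour 405, 483 and 623. It lay at 6.69, 10.61 and 9.70 in tumour 405, 483 and 616. The dimmer ranged only from 5.97 to 6.96.

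Among the gene lists, male-biased liver genes and the mitochondrial respiratory chain shifted furthest up and Kupffer cell genes furthest down. All 9 measured male-biased genes were higher in tumour after quantile normalization, with a list median of 0.64 relative to all genes (camera adjusted p = 0.00113; as deposited 0.80, 1.88e-09; adjusted p = 0.927 and 0.9995 with an estimated correlation), and of 1.07 without non-tumour 623 (4.89e-05). As deposited 2 of them rose, both over all genes and adjusted over the list alone: Cyp2d9, a male-specific steroid hydroxylase, by 3.04 ± 0.55 (SE, limma adjusted p = 0.00232, relative 3.51e-05), and Elovl3, a fatty acid elongase, by 2.19 ± 0.40 (adjusted p = 0.0133, relative 6.08e-05). As deposited the groups overlapped for both. Cyp2d9 lay at 7.22, 8.23 and 12.22 in non-tumour 405, 483 and 623, against 11.68 to 11.99 in the tumours. Elovl3 lay at 5.91, 5.52 and 7.82, against 7.75 to 8.41, and did not overlap after quantile normalization. Their calls were not followed with single arrays left out. After quantile normalization limma called 0 of the 9 male-biased genes over all genes, 1 (Elovl3) over the list alone and 2 higher unadjusted. Non-tumour 623 stood apart in sex: Xist, the RNA of the inactive X chromosome, was at 5.39 there and between 10.55 and 12.07 on the other 5 arrays, and the Y-linked Eif2s3y was at 9.48 there and at most 5.14 elsewhere, as deposited. The mean of the male-biased list, against its 6-array mean, was -1.34 in non-tumour 405 and -0.77 in non-tumour 483, but 0.67 in non-tumour 623, beside 0.61, 0.21 and 0.62 in tumour 405, 483 and 616. The female-biased list did not pass (median -0.24, adjusted p = 0.132), although Hao2, a hydroxyacid oxidase, passed (-1.94, limma adjusted p = 0.000753), the only 1 of its 10 members called over all genes or adjusted over the list alone as deposited. After quantile normalization limma called 0 of them, with 2 lower unadjusted. Relative to the median gene Hao2 did not pass (-1.46 ± 0.39, relative 0.0677).

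Of 25 respiratory chain genes 22 were higher in tumour after quantile normalization, with a list median of 0.42 (camera adjusted p = 6.83e-04; as deposited 0.67, 8.02e-11; adjusted p = 0.927 and 0.9995 with an estimated correlation). Among the members with the smallest p were the complex I subunit Ndufa1 (1.28 ± 0.49, SE, quantile-normalized) and the complex IV subunit Cox5b (0.90 ± 0.43), and limma called 0 members, with 1 higher at an unadjusted p under 0.05 on either scale. The list mean was lowest in non-tumour 405, at -0.72, and tumour 483 at -0.23 lay below non-tumour 483 and 623. Cell cycle genes shifted up by a median of 0.35 (29 of 37 higher, adjusted p = 0.00113; as deposited 0.27, 5.69e-04; adjusted p = 0.927 and 0.9995 with an estimated correlation), with Nusap1, a spindle protein, at 1.27 ± 0.49, while Mki67 had the opposite sign. Cenpe (-0.30), Melk (-0.29) and Tk1 (-0.24) were lower after quantile normalization, and each had a smaller p as deposited than Nusap1. Limma called 0 members of the cell cycle list, with 0 higher and 2 lower unadjusted as deposited and 3 and 0 after quantile normalization. Non-tumour 483 had the lowest mean of that list, -0.74. Genes of oxidative stress and NRF2 shifted up by 0.26 (18 of 24 higher, adjusted p = 0.0217; as deposited 0.45, 3.24e-04; adjusted p = 0.927 and 0.9995 with an estimated correlation), with Ephx1, the microsomal epoxide hydrolase, at 0.52 ± 0.21. Hmox1 (-0.57), Osgin1 (-0.61) and Sod1 (-0.06) were lower after quantile normalization, and each had a smaller p as deposited than Ephx1. Limma called 0 members of the NRF2 list, and 1 was higher unadjusted after quantile normalization and 0 as deposited.

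Kupffer cell and macrophage genes shifted down by a median of -0.58 (19 of 23 lower, camera adjusted p = 0.0212; as deposited -0.55, 5.39e-04; adjusted p = 0.927 and 0.9995 with an estimated correlation). Limma called 0 over all genes, 10 lower adjusted over the list alone and 13 lower unadjusted as deposited, but 0 lower over the list alone and 1 lower unadjusted after quantile normalization. Timd4 (-1.31 ± 0.96, SE, quantile-normalized) and Vsig4 (-1.52 ± 0.93), both receptors of resident Kupffer cells, were among the lowest. Without non-tumour 623 the list did not pass after quantile normalization (adjusted p = 0.452), nor as deposited (0.102), nor without tumour 405 (0.935). The list mean ranged from -1.47 in tumour 405 to 0.80 in tumour 483 and from -0.73 to 0.99 within non-tumour. Endothelial genes shifted up by 0.14 (14 of 26 higher, adjusted p = 0.00895; as deposited 0.19, 5.88e-04; adjusted p = 0.927 and 0.9995 with an estimated correlation). Cd34 (1.53 ± 0.39) and Emcn (1.66 ± 0.44), both of vascular endothelium, were the highest, whereas Vwf (-0.29 ± 0.36) was lower; limma called 0 members, with 2 higher unadjusted as deposited and 6 after quantile normalization. Lymphocyte genes shifted down as deposited (median -0.20, adjusted p = 0.00856; adjusted p = 0.9995 with an estimated correlation) but not after quantile normalization (-0.13, adjusted p = 0.0969), with 0 members called by limma and 4 lower unadjusted as deposited and 0 after quantile normalization.

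**Figure D3:**
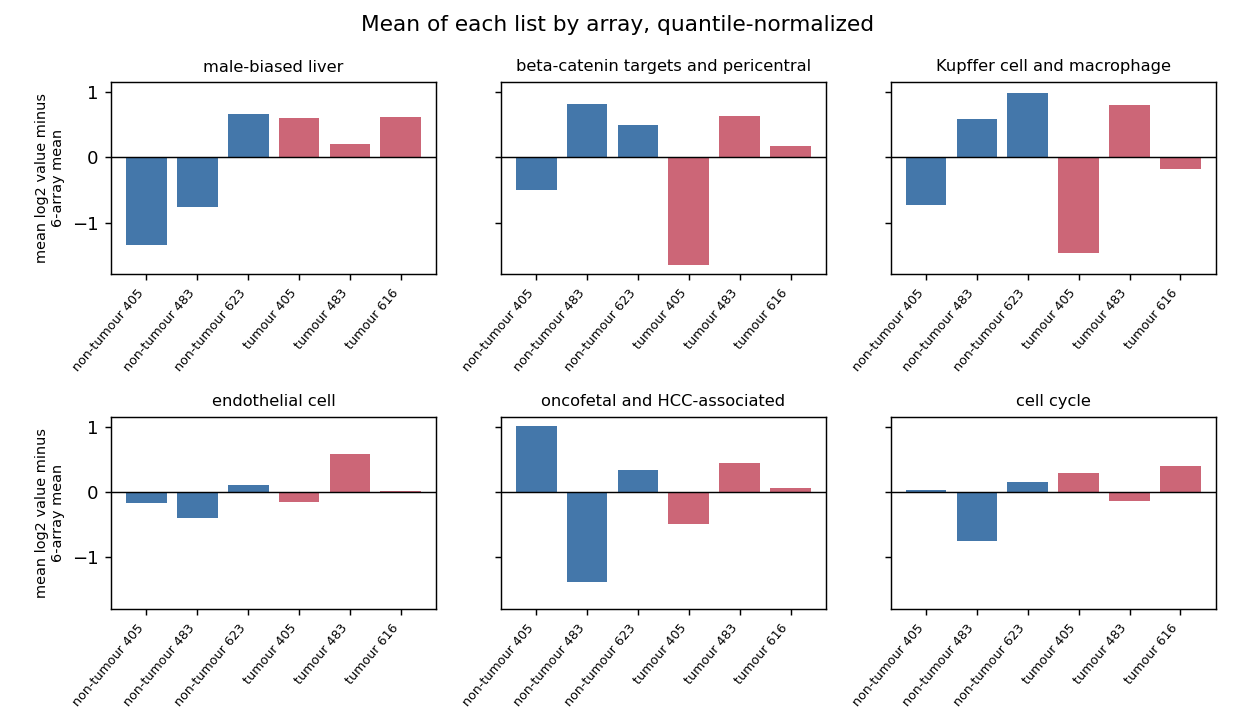
Mean log2 value of 6 gene lists on each array after quantile normalization, as the difference from the 6-array mean (bars; non-tumour blue, tumour red). The beta-catenin and pericentral list stood at -1.66 in tumour 405 and between -0.50 and 0.83 on the other arrays.

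Beta-catenin targets and pericentral genes shifted down as deposited (median -0.33, camera adjusted p = 0.0125) and after quantile normalization (-0.44, 0.0348, 19 of 21 lower) but not after median centring (adjusted p = 0.195) or with an estimated correlation (adjusted p = 0.927 and 0.9995 with an estimated correlation). Limma called 0 over all genes, 6 lower adjusted over the list alone and 9 lower unadjusted as deposited, but 0 and 0 after quantile normalization. Tumour 405 carried the shift, with Cyp2e1, a pericentral cytochrome P450, at 8.35 there against 11.86 to 12.98 on the other arrays, and without tumour 405 the list mean as deposited was 0.17 and the list did not pass (adjusted p = 0.0977), nor did it without non-tumour 483 (0.905). In total 13 lists passed as deposited, 9 after quantile normalization, 12 after median centring and 6 on all 3 scales in the same direction: male-biased, respiratory chain, cell cycle, NRF2, Kupffer cell and endothelial. With an estimated correlation 0 lists passed by camera on either scale, with 0 at an unadjusted p under 0.05 (smallest adjusted p = 0.9995 as deposited and 0.927 after quantile normalization), and by fry 0 passed (smallest adjusted p = 0.831 and 0.938). The 13 became 8 without tumour 616. As deposited, 3 of the 13 passed whichever array was left out: male-biased, respiratory chain and NRF2. The cell cycle list did not pass without non-tumour 483 (0.619) or tumour 616 (0.0717), where its mean of 0.29 became 0.06 and 0.18, or the endothelial list without tumour 483 (0.233; 0.31 became 0.11). The lymphocyte list did not pass without non-tumour 483 (0.197) or tumour 405 (0.131), where -0.30 became -0.16 and -0.15.

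A further 5 lists shifted up relative to all genes as deposited and did not pass after quantile normalization. They were cytochrome P450 genes (median 0.39, camera adjusted p = 5.85e-04; quantile-normalized 0.16, 0.593), imprinted genes (0.30, 0.00602; 0.22, 0.204), fatty acid oxidation (0.47, 0.00678; 0.11, 0.705), hepatocyte identity (0.30, 0.0219; -0.02, 0.705) and the unfolded protein response (0.37, 0.0408; 0.02, 0.769). Each had a camera adjusted p = 0.9995 with an estimated correlation as deposited. Before the median gene was taken off, the medians of these lists were all negative: -0.09, -0.18, -0.01, -0.18 and -0.11 in the same order. Adjusted over the list alone, as deposited, 1 cytochrome P450 gene was lower, 2 imprinted genes were higher and 1 lower, 1 fatty acid oxidation gene (Ppargc1a) was lower, 0 hepatocyte identity genes changed, with 0 unadjusted, and 1 gene of the unfolded protein list was lower. After quantile normalization 0 members of these 5 lists passed over the list alone, except 1 in the unfolded protein list that was higher, Atf3, a stress-induced transcription factor; unadjusted, at most 2 were higher and at most 1 lower in each list. Leaving out 1 array ended each of these 5 list calls: non-tumour 405 or tumour 616 for cytochrome P450 (camera adjusted p = 0.719 and 0.937), fatty acid oxidation (0.910 and 0.983), hepatocyte identity (0.536 and 0.267) and the unfolded protein response (0.408 and 0.0717), non-tumour 623 for the last 2 (0.154 and 0.128), tumour 483 for the unfolded protein response (0.138), and non-tumour 483 or tumour 483 for imprinted genes (0.197 and 0.233). The list mean shrank in most of these, as from 0.36 to 0.04 and 0.03 for cytochrome P450, but without non-tumour 623 it was kept for hepatocyte identity (0.24 and 0.24) and the unfolded protein response (0.22 against 0.18), as it was for the latter without tumour 616 (0.20). The gene lower in the unfolded protein list was Vldlr, the very low density lipoprotein receptor, which passed before the median gene was taken off (-1.53, limma adjusted p = 0.0251) but not relative to it (-1.05 ± 0.38, SE, relative 0.609). The reverse held for 2 lists, which were lower only after quantile normalization. Urea cycle and amino acid breakdown had a median of -0.16 (22 of 26 lower, adjusted p = 0.0348) against 0.20 as deposited (0.361), with Tdo2, which degrades tryptophan, at -0.86 ± 0.22. SR proteins and splicing regulators, the family of the deleted gene, had a median of -0.14 (30 of 38 lower, adjusted p = 0.0348) against -0.05 (0.361), with Ptbp2, a polypyrimidine tract-binding protein, at -0.69 ± 0.32. Both calls were lost with an estimated correlation (adjusted p = 0.927 with an estimated correlation). In both lists limma called 0 genes, also adjusted over the list alone, on either scale. Unadjusted, 0 urea cycle genes were higher and 2 lower after quantile normalization (0 and 1 as deposited), and 1 splicing regulator was higher and 0 lower, against the direction of the list (0 and 3 as deposited).

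The remaining lists passed on neither scale. As deposited, medians and camera adjusted p were 0.28 and 0.0633 for bile acid genes, 0.13 and 0.0949 for p53 targets, 0.18 and 0.158 for periportal genes, 0.23 and 0.254 for glycolysis, 0.24 and 0.270 for the insulin axis, 0.10 and 0.270 for ribosomal proteins, -0.01 and 0.270 for growth signalling, 0.14 and 0.463 for fatty acid synthesis, 0.16 and 0.571 for the acute phase and 0.06 and 0.616 for cholesterol synthesis. They were 0.05 and 0.616 for neutrophils, -0.09 and 0.846 for matrix and stellate cells, 0.02 and 0.864 for erythroid cells, 0.08 and 0.903 for mesenchymal transition, -0.09 and 0.919 for cholangiocytes, -0.00145 and 0.968 for interferon and -0.10 and 0.999 for adipocytes and muscle. Pdgfra, a stellate cell receptor, was the only member of these lists besides Cyp7a1 called over all genes (-1.59, limma adjusted p = 0.0211). Relative to the median gene it did not pass (-1.11 ± 0.39, SE, limma relative adjusted p = 0.534). As deposited Pdgfra lay at 4.78, 7.21 and 6.57 in tumour 405, 483 and 616, against 7.47 to 8.04 in non-tumour. Tumour 405 thus stood furthest from non-tumour. Adjusted over the list alone, as deposited, 1 bile acid gene, 1 periportal gene, 2 growth signalling genes (Etv5 and Egfr), 1 fatty acid synthesis gene and 2 matrix genes were lower, 1 neutrophil gene was higher and 1 lower, 2 cholangiocyte genes were higher and 2 lower, and Fabp4 of the adipocyte list was higher. After quantile normalization only Fabp4 passed over the list alone, and in the other lists of the last sentence limma called 0, with at most 1 gene higher and at most 3 lower unadjusted in each. In the other lists of this paragraph limma called 0 on either scale. Unadjusted, as deposited, 1 p53 target was higher and 1 lower, 5 interferon and 2 acute phase genes were lower, and 1 gene was lower in each of the glycolysis, insulin, ribosomal, erythroid and mesenchymal lists, while after quantile normalization 2 p53 targets and 1 ribosomal gene were higher and 0 genes lower. The sign of median, mean and test differed as deposited in mesenchymal transition, cholangiocytes, erythroid cells, adipocytes and muscle, and interferon. After quantile normalization they differed in the oncofetal, bile acid, fatty acid oxidation, cholangiocyte and adipocyte lists.

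**Figure D4:**
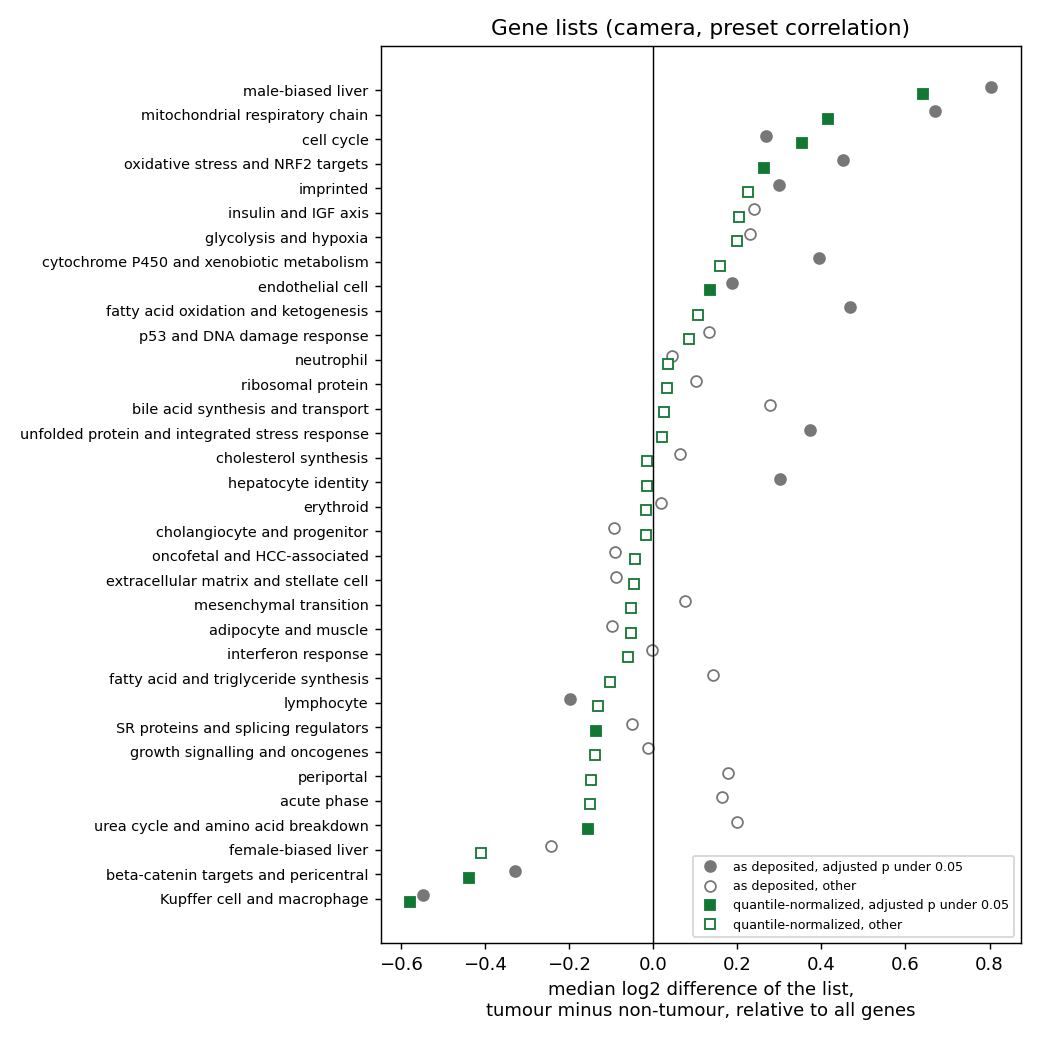
Median log2 difference, tumour minus non-tumour, of 34 gene lists relative to all genes, as deposited (grey circles) and quantile-normalized (green squares), filled where the camera adjusted p was under 0.05 with the preset correlation. Male-biased genes lay highest at 0.80 and 0.64 and Kupffer cell genes lowest at -0.55 and -0.58.

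The tumours did not vary more among themselves than the non-tumorous pieces. The median SD over genes was 0.40 log2 units among tumours and 0.50 among non-tumour arrays, a ratio of 0.79 with 3 arrays each, and the ratio was 1.01 without non-tumour 483 or without non-tumour 623 and 0.43 without tumour 483. A ratio as far from 1 occurred in 6 of the 10 splits of the arrays. Across genes, which are not independent replicates, the most similar arrays were non-tumour 623 and tumour 483 (r = 0.961, quantile-normalized) and the least similar non-tumour 405 and tumour 616 (r = 0.834).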

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

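Outside the comparisons above, 52625 features without a single gene name passed the same filter on dim features, and no control array set their background. All tests named here were made after the report's results were seen. As deposited 11 of these features were higher in tumour and 163 lower (limma, adjusted p under 0.05), which is why they were looked at. After quantile normalization limma called 0 higher and 0 lower of 52611, with 1065 higher and 677 lower at an unadjusted p under 0.05, against 88 and 10550 as deposited. The 1065 and 677 together were fewer than that threshold passes by chance among 52611 features. Why the calls made as deposited were lost was not tested, and no gene was assigned to the features.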

How the results depend on the processing

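Before alternatives, the genes higher in tumour were 14 and the genes lower in tumour 38, 13 lists shifted, the Srsf3 difference was 0.16 and the ratio of spreads 0.79; gene differences here are unscaled, list values are means relative to all genes, and the cause of a change was not tested unless stated. Quantile normalization or median centring gave 0 and 0 genes; the former turned hepatocyte identity (-0.0733) and the urea cycle (-0.21). Without a filter on dim features 59 genes were lower and Srsf3, whose dim features then entered, was -0.19. A pseudocount of 1 gave 60 lower, 64 gave 9 higher, adjusted p under 0.10 gave 68 lower, no trend 1 and 5, and robust eBayes 6 and 16. Array weights, whose fit did not converge, gave 701 and 7197, with Srsf3 -0.38, Cyp7a1 1.22, beta-catenin 0.31 and Kupffer -0.10, whose test turned. Camera with an estimated correlation and fry gave 0 lists. The random replicate block gave 0 and 0 genes and turned the test of beta-catenin (mean -0.45). The fixed replicate block, on the arrays of 405 and 483, gave 10 higher, 4 lower and 8 lists. Deviations from the group means of samples with a shared number correlated across genes at r = 0.30 for 405 and -0.00505 for 483, and the samples were not treated as paired. Leaving out each array gave 6 to 98 higher, 8 to 405 lower, 8 to 19 lists, Srsf3 0.01 to 0.43 and spread ratios 0.43 to 1.01, above 1 without non-tumour 483 or 623; an SD of 2 arrays has a lower median by construction. Signs turned, over the ranges given, for Afp (-2.59 to 0.0699) and bile acids (-0.25 to 0.36) without non-tumour 405, oncofetal (-0.58 to 0.53) and cholesterol (-0.37 to 0.34) without non-tumour 483, matrix (-0.40 to 0.28) and beta-catenin (-0.91 to 0.17) without tumour 405, interferon (-0.39 to 0.23) without tumour 483 or, at -0.23, non-tumour 405, and fatty acid oxidation and ketogenesis (-0.00749 to 0.42) without tumour 616.

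The rest were chosen after the data had been seen. The difference tested relative to the median gene gave 33 higher and 12 lower. Each gene's own variance gave 0 and 0 genes, as did each of the following combinations with quantile normalization. Without non-tumour 623, 7 lists shifted, with Srsf3 -0.0588, hepatocyte identity -0.12 and urea cycle -0.32. Unadjusted, 1357 genes were then higher and 371 lower, against 441 and 174 with all arrays, and the smallest limma adjusted p was 0.107. Without non-tumour 405, Afp was 0.43, hepatocyte identity -0.11, urea cycle -0.31, cytochrome P450 -0.13 and acute phase -0.31. Without tumour 405, hepatocyte identity was -0.0504, urea cycle -0.20, matrix 0.25 and beta-catenin 0.0900. The smallest limma adjusted p was then 0.110, with 189 genes higher and 83 lower unadjusted. With the replicate block, hepatocyte identity was -0.0775, urea cycle -0.23 and acute phase -0.23. Over the single genes and lists named, 780 and 595 values kept direction and side of the threshold, 178 and 66 lost a call, 19 and 43 gained one, 48 and 84 changed sign without a call, and 3 and 26 changed sign with a call on either side, all given above. List tests do not use the eBayes setting. Exon-use alternatives were not run, since the table was not at exon level.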

Other observations

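The tests, the test of the relative difference included, and the genes of this part were chosen after the results were seen. Among the 14 genes that rose, Defb1, an epithelial defensin, had the largest relative difference, 3.66 ± 0.57 (SE, n = 3 each, limma adjusted p = 4.81e-05). Others outside the named set were Mogat2, an acyltransferase of intestinal fat absorption (3.17 ± 0.54, 0.000541), Scd3, a stearoyl-CoA desaturase (2.90 ± 0.56, 0.00852), Calml4, a calmodulin-like protein (2.86 ± 0.56, 0.0134), and Wfdc2, a secreted epithelial protease inhibitor (2.82 ± 0.49, 0.00137). Vil1, the villin of microvilli, rose by 2.25 ± 0.38 (limma adjusted p = 0.00233), most in tumour 483. As deposited Vil1 lay at 6.64, 9.30 and 6.04 in tumour 405, 483 and 616, against 5.24, 5.09 and 6.35 in non-tumour 405, 483 and 623. None of these genes passed after quantile normalization, where limma called 0 genes. On that scale 441 genes were higher and 174 lower unadjusted, together fewer than the 851 given by chance. Defb1 then stood at 6.41, 4.93 and 10.70 in non-tumour 405, 483 and 623, against 10.09 to 11.89 in the tumours, so that non-tumour 623 overlapped them. Scd3 stood at 11.14, 4.73 and 11.33 in these non-tumour arrays, against 10.77 to 12.02 in the tumours, so only non-tumour 483 lay below them. Mogat2 stood at 6.60, 5.14 and 8.93, against 9.92 to 10.31 without overlap.

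Values of some list members that were not called over all genes on either scale follow. After quantile normalization Egfr, the EGF receptor, stood at -1.78 ± 0.51 relative to non-tumour (SE, n = 3 each) and Etv5, an ETS factor downstream of growth signalling, at -0.95 ± 0.27. The stress genes Gadd45b and Atf3 stood 1.97 ± 0.49 and 1.52 ± 0.30 higher. The lipid synthesis genes Acaca, Lpin1, Acly and Fasn stood between -1.09 and -1.35, but Cidec (1.28), Dgat1 (0.90) and Thrsp (0.64) of the same list had the opposite sign, and the list did not pass.

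The excess of genes lower in tumour was weighed against the scale of the arrays. Of the genes with an unadjusted p under 0.05, 94.0% were lower as deposited, 28.3% after quantile normalization and 58.8% after median centring. Both scalings centre the arrays and so remove a common shift whatever caused it. The difference was not a uniform shift. At the 25th percentile tumour 405 and 616 (36.0 and 40.0) lay below every non-tumour array (53.5 to 85.1). At the 99th percentile all tumours (2967 to 3489) lay within the non-tumour range (2738 to 4624). Among the dimmer features a difference in scale cannot be told apart from a fall in these RNAs. For the calls, each of the 52 genes (100%) had an SD of its own above the one the test used, against 32.8% of all genes, and with each gene's own variance limma called 0 (6 higher and 958 lower unadjusted), so the calls rest on the pooled variance. The 10 splits of 6 arrays are too few for a share under 0.05. As deposited, as many genes were called in 3 of them (52 in the real split, 267 in the highest other) and as many lists in 8 (13 and 22). After quantile normalization 9 lists were called in the real split and 2 to 13 in the others. On that scale 6 of the 10 splits had as many genes at an unadjusted p under 0.05 (615 in the real split, 1816 in the highest other). The split with 267 called 0 after quantile normalization, with 1161 unadjusted. Only 1 of the 10 splits called any gene on that scale, so this loss does not explain the 267. Simulated data, with each gene's estimated SD taken as true, gave 132 to 163 wrong calls as deposited. That number may be too high for these arrays, where the lowest other split called 4. Structure among the samples still cannot be told apart from calls made in error. No biological explanation was tested.

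Afp, Gpc3 and Akr1c18 were highest in non-tumour 405, and Gpc3 and Akr1c18 also stood above every tumour in non-tumour 623. In non-tumour 405 each gene stood at least 3.88 log2 units above the highest tumour after quantile normalization. These genes were taken up here because they were lower in tumour and highest in non-tumour 405, so that gap follows from the choice. Whether non-tumour 405 held RNA of the sampled tumours therefore cannot be told from the gap. An exchange of the arrays numbered 405 cannot be told apart from a correct label: tumour 405 correlated better with the other tumours than with the other non-tumour arrays, by 0.0415 across genes, but non-tumour 405, 483 and 623 and tumour 483 did not correlate better with their own group. A candidate explanation for non-tumour 405 is an unsampled lesion within the piece; it was not tested, and it does not address non-tumour 623.

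Male-biased genes stood high in tumours that expressed Xist. Tumours of male mice are argued against, since the 4 features of the Y-linked Eif2s3y, Kdm5d and Uty above the dim threshold in non-tumour 623 lay at least 2.20 log2 units lower in the highest tumour (0.84 and 0.87 for 2 dimmer Uty features). The limit to brighter features was set after all 6 values had been seen, because dim values near the floor exclude nothing; over all 6 features the bound of 1 log2 unit would not be met. The scale of the arrays is argued against as the whole cause, since the list median was 0.64 relative to all genes after quantile normalization and passed with the preset correlation, though not with an estimated one (adjusted p = 0.927 with an estimated correlation) or by fry (0.938). As large a shift of the list mean occurred in 2 of the 10 splits (0.93 in the real split, 1.22 in the highest other), and 10 splits are too few for a share under 0.05. The Xist-expressing tumours may have lost part of the sex bias of liver expression, a hypothesis found and examined on the same data. The low values of non-tumour 405 and 483 rather than a change in tumour remain as open an explanation, and the sex of the animals was not given in the sources used here.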
